A study of Mus musculus with 882 samples.

How the data were processed

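Single-cell transcriptomes of the mouse retina were measured in 3 sets of samples, 882 in all. The first set is 14 droplet (10x) libraries of wild-type CD1 retinas at 10 ages from E11 to P14 (E, embryonic day; P, postnatal day), with 2 libraries each at E14, E18, P2 and P8 and 1 at each other age. The second set is 4 droplet libraries of P14 retinas on a mixed CD1 and C57Bl6 background that carry a Cre-GFP transgene, in which Cre recombinase is made in retinal progenitors: 2 libraries with 1 floxed copy each of Nfia, Nfib and Nfix (here het) and 2 with both copies of all 3 genes floxed (here tCKO). The third set is 864 single cells in the labels, 288 per age at E14, E18 and P2. They were sorted as retinal progenitors, though the deposited annotation puts some of them in other classes. They were prepared by an adapted Smart-seq2 protocol, a plate method for whole transcripts. Nfia, Nfib and Nfix encode transcription factors of the nuclear factor I family.

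The deposited values of both droplet tables are counts: UMIs (unique molecular identifiers, each marking 1 captured transcript) per cell and gene, not normalised. Their sum over genes equalled the total that the deposited cell table gives for every cell. The wild-type table holds 120804 cells and 27998 genes, of which 21413 had a UMI. The het and tCKO table holds 26537 cells and 20666 genes with a UMI. The deposited Smart-seq2 values are another unit: abundances scaled within each cell to an estimated number of transcripts, which sum in each cell to the total in the cell table. How those totals were set is not given in the sources used here. That table holds 747 cells (195 at E14, 283 at E18 and 269 at P2), from 3 plates per age, with 20208 genes above 0 of 28446. Per the submitters' processing notes, Cell Ranger 1.2.1, HISAT, SAMtools and Cuffnorm were used with builds mm10 and GRCm38, without versions of the last 3 tools. Which step each served and how cells were filtered are not given in the sources used here. Every cell carries a class in the deposited cell tables, and these classes were used as the authors annotated them. RPCs (retinal progenitor cells) are all cells annotated as early, late or unspecified RPCs. Neurogenic cells, the progenitors about to leave the cell cycle, are a class of their own.

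UMI counts were summed over the cells of each class in each library. Classes were tested with at least 30 cells per wild-type library, or at least 20 in each of the 4 het and tCKO libraries. Sums were compared with edgeR 4.0.16 in R 4.3.3: TMM normalisation, filterByExpr, robust quasi-likelihood fits, and Benjamini-Hochberg adjustment over all genes tested, with a threshold of 0.05. Every adjusted p of a gene is from this edgeR test unless another tool is named. A gene is said to rise, fall or change only where it passed that threshold, and changes are log2 fold changes with the standard error (the size of the change over the square root of the F statistic). Levels are the gene's UMIs scaled by the UMIs of the sum (edgeR's CPM) with the SD of the 2 libraries. The 3 comparisons of RPCs between ages came from 1 fit of the RPC sums of 12 libraries with age as a factor, which leaves 3 residual degrees of freedom. The age trend used the order of the ages as a number. The labels do not say that libraries came from separate animals or litters, so the p-values measure the spread between these libraries, which may be technical. Replicates of a group differed beyond sampling noise, with a chi-square per degree of freedom between 8.41 and 48.05 in the pairs of libraries checked.

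The 30 gene lists hold 406 genes. Lists were tested with camera in limma 3.58.1 on the logCPM of the same sums (prior count 2) with a preset correlation of 0.01, adjusted over the lists of a comparison. Each was tested again with the correlation estimated from the data. The lists are RPC core, early temporal, late temporal and gliogenic, G1/S, G2/M, cell cycle exit, Notch pathway, neurogenic bHLH, early-born fate, late-born fate, rod, cone, bipolar, amacrine, horizontal, RGC (retinal ganglion cell), Müller glia, reactive glia, astrocyte, vascular, microglia, red blood cell, pigment epithelium and lens, immediate early and heat shock, interferon response, p53 and stress response, cholesterol synthesis, glycolysis, mitochondrial genome and synapse. Some genes are in more than 1 list: Otx2 is in both the late-born fate and bipolar lists.

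The comparisons, the gene lists, the class minimums, the first set of alternatives and the genes to name were chosen before the data were examined. In every comparison Nfia, Nfib and Nfix are named. So are the 10 largest rises and 10 largest falls among genes past the threshold with an average logCPM of at least 5 and no overlap between the libraries of the groups. For the trend these are the largest slopes. Up to 4 members per list with the smallest adjusted p are also named, and 5 genes with the smallest adjusted p where the difference between 2 classes was tested. For Smart-seq2 they are the 5 largest rises and falls among the 3000 genes with the highest mean. Mitochondrial genes, Xist, Y-linked genes, hemoglobins and unnamed gene models are counted but not named from the largest changes. The text gives a subset of these genes, and a few that these rules select are not reported here.

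Tests of RPCs, neurogenic cells and photoreceptor precursors between het and tCKO, and the test of rods against amacrine cells, were added after the class sizes had been seen. Bipolar cells and Müller glia, which were planned, fell under the minimum of 20 cells in a tCKO library and have values but no test. A gene with a count of 0 in a group is given as a lower bound against 3 counts over the group. A gene with 1 to 3 counts is given as a ratio with its exact 95% counting interval. Intervals and floors cover counting error only.

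Class shares are the percent of all barcodes of a library. Cells annotated as doublets, at most 17.96% of a library (P8 replicate 2), stay in these totals and in the whole-retina sums, and are in no sum of another class. Their relation to age was tested over the 14 libraries with 100000 permutations (two-sided), adjusted over 13 classes. Shares of het and tCKO were compared by an exact permutation test, and also with edgeR on cell numbers. Smart-seq2 cells name no animal, so each age is 1 sample. Means over cells were compared as log2 ratios with a pseudocount of 1, with no test. List medians were set against 10000 random lists of the same size.

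The fits were tested on simulated data, in which 200 genes of the deposited sums were changed. For RPCs of P2 against E14, 25 of 100 genes changed by log2 1 were called and 99 of 100 changed by log2 2, with 6 of 130 calls false. For rods these numbers were 12 of 89, 80 of 97 and 6 of 98. For amacrine cells they were 19 of 99, 90 of 94 and 6 of 115. In the RPC simulation 200 of 14096 genes were changed, while 5318 of 14463 were called in the data. With fewer changed genes the adjustment is stricter, so the RPC rates need not hold for the reported comparison.

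Alternatives were another normalisation (median-ratio size factors), no filter on low counts, DESeq2 1.42.0, cells with at least 1000 UMIs only, leaving out each library in turn, and only the libraries of the 2 ages. Also tried were an estimated correlation for lists and, for Smart-seq2, other pseudocounts and scalings. Gene positions are from GENCODE M21 (Ensembl 96, GRCm38). Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. The P8 libraries hold fewer than 30 RPCs, and the E11, E12, P8 and P14 libraries fewer than 30 neurogenic cells, so these sums were left out.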

Results

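The wild-type droplet data hold 14 libraries at 10 ages. The total depth was 31587678 UMIs from 9364 cells at E11 and 13563444 from 1610 cells at E12. At E14 replicate 1 held 22608181 UMIs from 16154 cells and replicate 2 held 30318946 from 10790 cells. At E16 there were 5549914 UMIs from 5401 cells. At E18 replicate 2 held 32688194 from 11414 cells and replicate 3 held 28604149 from 11597 cells. The P0 library held 21980613 UMIs from 9925 cells. At P2 replicate 2 held 19606198 from 8070.0 cells and replicate 3 held 20600453 from 9893 cells. The P5 library held 8968492 from 6756 cells. At P8 replicate 1 held 11452861 from 8252 cells and replicate 2 held 3305907 from 3475 cells. The P14 library was the shallowest, with 2823648 UMIs from 8103 cells and a median of 271 UMIs per cell, against 8048 at E12. Of the P14 mutant series, het replicate 1 held 26471806 UMIs from 6148 cells and het replicate 2 held 8002451 from 5341 cells. The tCKO replicates 1 and 3 held 29893046 from 9378 cells and 36107374 from 5670.0 cells. The Smart-seq2 cells had median totals of 15188 estimated transcripts at E14, 15064 at E18 and 8304 at P2.

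The first question was how the shares of annotated cells changed with age. RPCs made up 91.4% of cells at E11 (1 library; exact 95% interval 90.85 to 92.0), 59.1% ± 3.09 at E14 (SD, n = 2), 42.3% ± 0.447 at P2 (n = 2) and 10.3% at P5 (1 library, 9.56 to 11.0). Retinal ganglion cells, the output neurons, peaked early, at 17.2% ± 0.332 at E14 (n = 2) and 18.4% at E16 (1 library, 17.4 to 19.5), and were 2.24% ± 0.694 at E18 (n = 2). The mean share of neurogenic cells at each age from E14 to P2 was between 9.74% and 12.2%. Rods went from 0 of 9364 cells at E11, which allows a share of up to 0.0320%, to 4.21% ± 0.273 at P2 (n = 2) and 23.4% at P5 (1 library, 22.4 to 24.4). Müller glia, the main glial cells of the retina, were 16.6% of cells at P5 (1 library, 15.7 to 17.5) and 17.5% at P14 (1 library, 16.6 to 18.3), but 0.478% ± 0.179 at P8 (n = 2). Amacrine cells were 16.5% ± 1.04 at E18 (n = 2), 0.222% ± 0.0289 at P8 (n = 2) and 0.136% at P14 (1 library). The P14 het libraries, on another background, held 28.9% and 11.4%. So the shares of deposited cells, above all the late ones, need not be those of the tissue, and the cause was not tested.

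**Figure D1:**
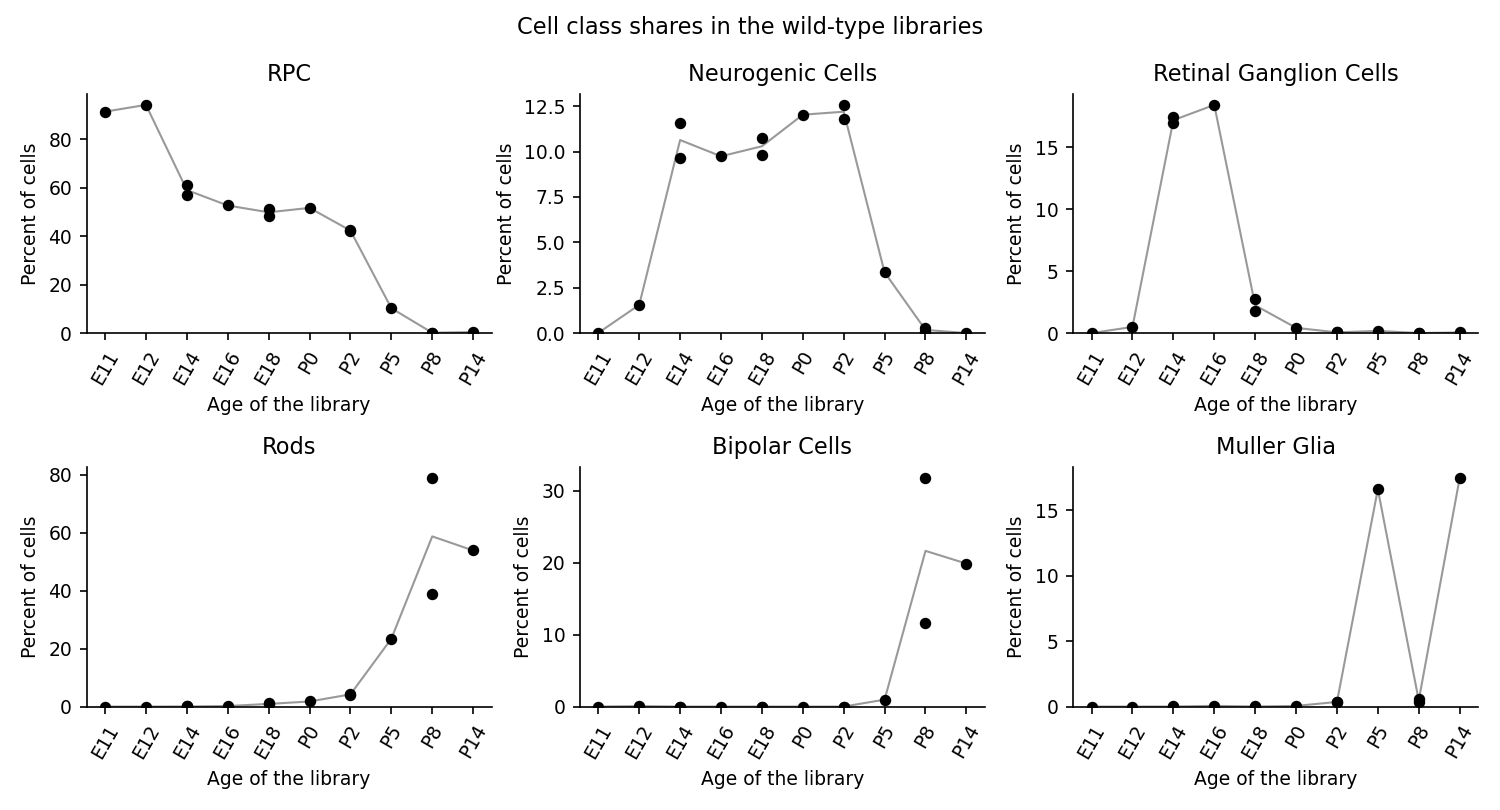
Percent of each library's cells in 6 annotated classes (y axes) against age (x axes), each point 1 library and lines through the mean of each age. RPCs went from 91.4% at E11 to 10.3% at P5, and rods from 0 at E11 to 23.4% at P5.

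Over the 14 libraries, 5 of 13 classes had a rank correlation with age that passed the permutation test. RPCs fell (Spearman rho -0.965, adjusted p = 6.5e-05; Pearson r -0.949, adjusted p = 0.00013). The raw p of 1e-05 behind these is the smallest that the permutations can give. Rods rose (rho 0.988, adjusted p = 6.5e-05; r 0.758, adjusted p = 0.00182). For cones rho was 0.756 (adjusted p = 0.00887, permutation) and r 0.699 (adjusted p = 0.0174). For bipolar cells rho was 0.646 (adjusted p = 0.0372, permutation) and r 0.654 (adjusted p = 0.0144). For Müller glia rho was 0.900 (adjusted p = 0.00017, permutation) but r was 0.531 and did not pass (adjusted p = 0.117). Without the 2 libraries farthest from the median age (E11 and P14) r was -0.923 for RPCs, 0.724 for rods, 0.602 for cones, 0.591 for bipolar cells and 0.343 for Müller glia. Red blood cells fell by r only (r -0.608, adjusted p = 0.00425, permutation). The annotated split of RPCs into early and late switched between E16 and E18: late RPCs were 0.445% and 8.82% of RPCs in the E14 libraries, 2.95% at E16, and 97.9% in both E18 libraries.

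The central comparison asks which genes differ between RPCs of P2 and E14, the ages on either side of that switch. The 3 Nfi genes rose together. Nfia (ENSMUSG00000028565; GRCm38 chromosome 4, 97772734 to 98118874) rose by log2 3.11 ± 0.14 (adjusted p = 3.4e-06), from 14.0 ± 1.57 to 121 ± 11.7 CPM (n = 2 each). Nfib (ENSMUSG00000008575; chromosome 4, 82290173 to 82705750) rose by 2.68 ± 0.12 (adjusted p = 3.1e-06), from 47.5 ± 0.154 to 305 ± 15.4 CPM. Nfix (ENSMUSG00000001911; chromosome 8, 84699876 to 84800344) rose by 7.12 ± 0.21 (adjusted p = 1.2e-06), from 0.853 ± 0.0361 to 121 ± 7.58 CPM. Across the other ages Nfia climbed from 2.50 CPM at E11 to 28.8 at E16 and 248 at P5. Nfib went from 38.0 CPM at E11 to 83.1 at E16 and 630.3 at P5.

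**Figure D2:**
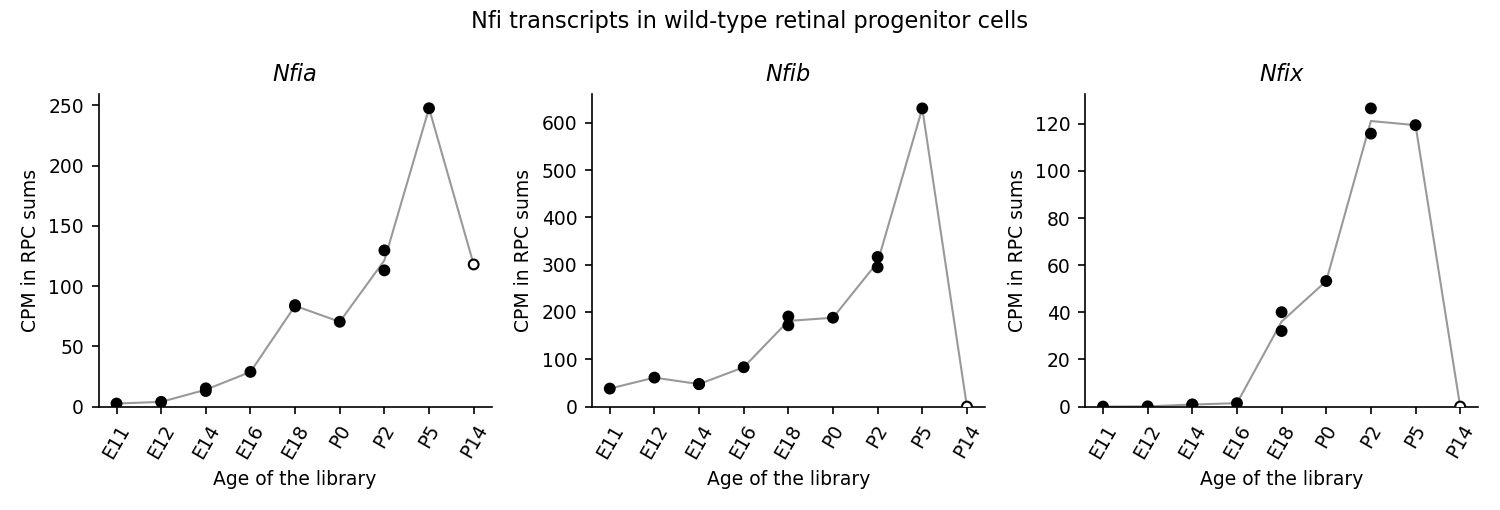
CPM of Nfia, Nfib and Nfix in RPC sums (y axes) against age (x axes), each point 1 library and lines through the mean of each age; P8 is left out. All 3 were higher in both P2 libraries than in both E14 libraries; the hollow P14 point rests on 34 cells and 11243 UMIs, where a count of 0 allows up to 267 CPM.

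In RPCs 5318 of 14463 genes differed between P2 and E14: 2494 were higher and 2824 lower at P2, and 6819 had an unadjusted p under 0.05. Without P2 replicate 2 the count was 2588, and without P2 replicate 3 it was 2713. Those fits leave P2 with 1 library, assumed to vary like the others, as in each such fit below. Genes of glia were among the largest rises. Rlbp1, which encodes the retinaldehyde-binding protein of Müller glia, rose by log2 6.52 ± 0.24 (adjusted p = 1.9e-06), from 3.06 ± 1.17 to 289 ± 8.35 CPM. Car2, a carbonic anhydrase gene, rose by 5.03 ± 0.13 (adjusted p = 1.2e-06; 18.8 ± 1.24 to 617 ± 3.10 CPM), and Crym, a thyroid hormone-binding crystallin gene, by 6.29 ± 0.54 (adjusted p = 6.1e-04). Ccnd2, a D-type cyclin gene, had a change of -5.71 ± 0.37 (adjusted p = 7.1e-05; 246 ± 58.8 to 4.67 ± 2.85 CPM). Trpm1, an ion channel gene later used by bipolar cells, changed by -6.67 ± 0.61 (adjusted p = 2.7e-04). Eno1 (log2 -2.74) and Hspa8 (-3.68) also fell, and both were higher again at P5. A difference between library batches, weighed under the flagged results, may thus add to the genes called here.

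The early temporal list fell almost whole: 17 of 18 genes fell and 0 rose (17 and 0 adjusted over the list alone). Fgf15, a secreted growth factor gene, fell from 2143 ± 336 to 229 ± 4.52 CPM (log2 -3.23 ± 0.19, adjusted p = 1.2e-05). Crabp2, which encodes a retinoic acid-binding protein, changed by log2 -3.44, the transcription factor gene Foxp1 by -2.84 and the RNA-binding protein gene Igf2bp1 by -1.89. The late temporal and gliogenic list rose in 16 of 22 genes and fell in 1 (16 and 1 adjusted over the list alone), led by Nfix, Nfib, Nfia and the transcription factor gene Sox8 (4.04). The Müller glia list rose in 13 and fell in 4 of 21 (13 and 4 adjusted over the list alone), with Cd9 at 3.85, Dbi at 2.60 and the receptor gene Gpr37 at 3.34.

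Most called genes of the early-born fate and RGC lists fell, and those of the late-born fate list rose. The early-born fate list fell in 12 and rose in 2 of 16 genes (12 and 3 adjusted over the list alone), with Isl1 at -3.58 and Thrb at -2.26, while Prox1 rose by 1.98. The RGC list fell in 10 of 16 and rose in 0 (10 and 0 adjusted over the list alone), with Pou4f2, the ganglion cell transcription factor gene, at -4.01. Ganglion cells were 17.2% of cells at E14 and 0.0551% at P2, and free RNA from them in RPCs was not measured. The late-born fate list rose in 10 and fell in 0 of 13 (11 and 1 adjusted over the list alone). Its rod transcription factor gene Nr2e3 was at least 394-fold higher, and Nrl had a ratio of 169.7 (95% counting interval 57.5 to 828). The rod list rose in 17 and fell in 1 of 21 (17 and 1 adjusted over the list alone), at low levels: Sag, the rod arrestin gene, went from 0.261 to 31.8 CPM. P2 amacrine cells, which do not use rod genes, also held them: Nr2e3 gave 0.0872 UMIs per cell in P2 RPCs and 0.0456 in P2 amacrine cells.

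Camera called 6 more lists with the preset correlation, none of which held with an estimated one (adjusted p of at least 0.319). The neurogenic bHLH list rose in 11 and fell in 3 of 17 (12 and 3 adjusted over the list alone), with Hes6 at 1.93. The Notch pathway list rose in 10 and fell in 2 of 17 (10 and 3 adjusted over the list alone), with Dll1 at 1.75 and Notch1 at 1.53. The G2/M list rose in 13 of 20 and fell in 0 (15 and 0 adjusted over the list alone), by modest amounts such as 1.03 for Kif23 and 0.86 for Ube2c. The cell cycle exit list rose in 7 and fell in 2 of 12 (8 and 2 adjusted over the list alone), with Cdkn2c at 2.36 and Cdkn1c at -2.37. The immediate early and heat shock list rose in 11 and fell in 2 of 16 (11 and 2 adjusted over the list alone), with Fos at 1.88 and Egr1 at 2.04. The red blood cell list fell in 5 of 7 and rose in 0 (5 and 0 adjusted over the list alone). Red blood cells were 0.317% of cells at E14 and 0 at P2, and free RNA from them was not measured.

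The other 17 lists, each given as rose and fell of the genes measured, then both numbers adjusted over the list alone, were not called by camera. RPC core had 5 and 4 of 14 (6 and 4), G1/S 3 and 3 of 20 (3 and 3), and cone 5 and 1 of 9 (5 and 1). Bipolar had 6 and 3 of 13 (6 and 4; median 0.53, mean -0.73, camera up but not called, adjusted p = 0.617), amacrine 2 and 1 of 13 (2 and 1), and horizontal 2 and 4 of 9 (3 and 4). Reactive glia had 1 and 3 of 10 (1 and 3), astrocyte 2 and 1 of 4 (2 and 1), and vascular 2 and 4 of 11 (3 and 4). Microglia had 0 of 9 either way by edgeR (0 and 0). Pigment epithelium and lens had 1 and 3 of 11 (1 and 4), interferon response 2 and 0 of 10 (2 and 0), and p53 and stress response 2 and 5 of 13 (2 and 5). Cholesterol synthesis had 1 and 7 of 16 (1 and 7), glycolysis 7 and 3 of 19 (8 and 4), mitochondrial genome 1 and 2 of 11 (1 and 1), and synapse 5 and 3 of 20 (5 and 3). Within glycolysis Pfkp rose by 2.64. By camera with the preset correlation, 13 of the 30 lists were called, 9 up and 4 down, among them early temporal (adjusted p = 3.6e-09) and late temporal and gliogenic (1.5e-08). None held: the lowest adjusted p was 0.319 with an estimated correlation.

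The step from E14 to E18 was compared to place the change before birth. All 3 Nfi genes had already risen: Nfia by log2 2.57 ± 0.14 (adjusted p = 2.0e-05; 83.7 ± 0.817 CPM at E18, n = 2), Nfib by 1.93 ± 0.12 (adjusted p = 3.1e-05; 181 ± 13.2 CPM) and Nfix by 5.38 ± 0.21 (adjusted p = 6.5e-06; 36.0 ± 5.65 CPM). Sfrp2, a gene for a secreted Wnt modulator of early RPCs, went from 2494 ± 916 to 193 ± 33.1 CPM (log2 -3.69 ± 0.27, adjusted p = 1.1e-04). Hopx, a homeodomain gene found in stem cells, rose by 4.18 and Sox8 by 3.97. Prdm1, a photoreceptor fate gene, rose by 2.31, while the Notch ligand gene Jag1 changed by -3.12. The early temporal list fell in 13 of 18 genes and rose in 0 (15 and 0 adjusted over the list alone). The glycolysis list rose in 11 of 19 and fell in 0 (12 and 1 adjusted over the list alone), with Pfkp at 2.35, Tpi1 at 1.41 and Pfkl at 1.18.

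Between E14 and E18, 2735 genes differed, 1442 higher and 1293 lower at E18, and 4881 had an unadjusted p under 0.05. The count was 792 without E18 replicate 2, 882 without E18 replicate 3 and 5732 without E14 replicate 2. Camera called 17 lists, 13 up and 4 down, and none held: the lowest adjusted p was 0.344 with an estimated correlation.

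From E18 to P2 the Nfi genes diverged in size. Nfix rose by log2 1.75 ± 0.14 (adjusted p = 5.9e-04). Nfia rose by 0.54 ± 0.13 (adjusted p = 0.0227) and Nfib by 0.75 ± 0.11 (adjusted p = 0.0046), but the call of Nfia ended with DESeq2 and without any 1 of the 4 libraries, and that of Nfib without E18 replicate 3, P2 replicate 2 or P2 replicate 3. Dbi, which encodes an acyl-CoA-binding protein abundant in glia, rose by 2.47 ± 0.17 (adjusted p = 3.0e-04), from 761 ± 86.8 to 4210 ± 344 CPM. Fgf15 fell again, by 2.58 ± 0.18 (adjusted p = 3.8e-04), and the asparagine synthetase gene Asns changed by -2.34. The rod list rose in 12 of 21 genes and fell in 0 (14 and 0 adjusted over the list alone), with Nr2e3 at 2.43 and Sag at 3.34. Cholesterol synthesis fell in 9 of 16 and rose in 0 (10 and 0 adjusted over the list alone). The RGC list fell in 7 of 16 and rose in 0 (10 and 0 adjusted over the list alone). Ganglion cells went from 2.24% of cells at E18 to 0.0551% at P2, and free RNA from them was not measured.

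Between E18 and P2, 2714 genes differed, 1141 higher and 1573 lower at P2, and 5114 had an unadjusted p under 0.05. The count was 262 without P2 replicate 2, 326 without E18 replicate 3, 406 without P2 replicate 3 and 517 without E18 replicate 2. Some of the largest falls did not continue with age. Of 32 genes that fell at least 4-fold with an average logCPM of at least 5, the P5 library lay nearer to E18 for 25 and nearer to P2 for 7. Eno1, an enolase gene, was at 2126 and 2205 CPM in the E18 RPCs, 161 and 266 at P2 and 1001 at P5. Hspa8, a heat shock gene, was at 1169 and 1166 CPM at E18, 66.6 and 123 at P2 and 425 at P5. Fgf15 and Asns were among the 7 that stayed near the P2 level at P5. Camera called 10 lists, 5 up and 5 down, and none held: the lowest adjusted p was 0.518 with an estimated correlation. With only the libraries of the 2 ages edgeR called 5676 genes, and DESeq2's own test called 742.

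The age trend fits a straight line over all 9 ages with enough RPCs, so that a departure from the line counts as spread. A step or an end library can also give a slope. The last point, P14, rests on 34 RPCs with 11243 UMIs, all annotated as early. Per age step Nfia rose by log2 0.82 ± 0.10 (adjusted p = 7.1e-05), Nfib by 0.49 ± 0.08 (adjusted p = 5.5e-04) and Nfix by 1.38 ± 0.23 (adjusted p = 8.8e-04). The calls of Nfia and Nfix ended where ages were only split into before and after birth. Lin28b, an RNA-binding protein gene of early development, had a slope of -1.11 ± 0.06 (adjusted p = 2.7e-08), Jag1 of -1.36 and Sfrp2 of -0.92. Rlbp1 rose by 1.08 per step. The rod list rose in 17 of 19 genes and fell in 0 (17 and 0 adjusted over the list alone), with Pde6b, the rod phosphodiesterase gene, at 1.92 and Prph2 at 1.71. Red blood cell genes fell in 6 of 6 and rose in 0 (6 and 0 adjusted over the list alone). Red blood cells went from 6.66% of cells at E11 to 0.284% at P14, and free RNA from them was not measured. In all 4225 of 13332 genes had a slope past the threshold, 1895 up and 2330 down, with 5618 at an unadjusted p under 0.05. Camera called 13 lists, 11 up and 2 down, and only the rod list held, with an adjusted p of 0.0132 with an estimated correlation. Rods went from 0 of the cells at E11 to 53.86% at P14. Rod RNA from other cells is weighed under the flagged results, for P2 only.

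Neurogenic cells were compared between P2 and E14 to see whether cells leaving the cycle changed like RPCs. Nfia rose by log2 3.36 ± 0.23 (adjusted p = 4.9e-07) and Nfib by 3.65 ± 0.17 (adjusted p = 3.1e-08), from 21.0 ± 2.19 to 261 ± 21.3 CPM (n = 2 each), and Nfix was at least 162-fold higher (386 UMIs against 0). Irx5, a homeobox gene of bipolar cells, rose by 5.42 and the bipolar gene Lhx4 by 3.84. Pou4f2 changed by -4.98, Onecut1, a horizontal cell factor gene, by -3.73, and Dlx1 by -3.62. Free RNA from ganglion cells or other early-born cells was not measured in neurogenic cells. Otx2, the photoreceptor and bipolar factor gene, rose by 1.12. The late temporal and gliogenic list rose in 18 of 20 genes and fell in 0 (18 and 0 adjusted over the list alone). The G2/M list fell in 19 of 20 and rose in 0 (19 and 0 adjusted over the list alone), with Hmmr at -1.35 and Nusap1 at -1.02. The cholesterol synthesis list fell in 11 of 16 and rose in 0 (11 and 0 adjusted over the list alone). In all 3293 of 11250.0 genes differed, 1635 higher and 1658 lower, and 4583 had an unadjusted p under 0.05; the count was 1589 without P2 replicate 3 and 1639 without P2 replicate 2. Camera called 13 lists, 8 up and 5 down, and none held. The lowest was late temporal and gliogenic, adjusted p = 0.05996 with an estimated correlation, and G2/M had adjusted p = 0.0611 with an estimated correlation. This comparison uses the same P2 libraries, so the batch difference weighed under the flagged results may add to it too.

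The Smart-seq2 cells give the same ages by another method, with each age as 1 sample and no replicates. Fgf15 had a mean of 63.6 estimated transcripts per cell at E14, 27.4 at E18 and 2.52 at P2 (log2 of P2 over E14 -4.20). Sfrp2 went from 18.1 to 1.89 and 0.340, and Crabp2 from 11.4 to 2.83 and 0.413. Dbi went from 10.0 to 19.8 and 50.8. Nfix went from 0.0228 to 0.474 and 0.683, and Nfib from 0.119 to 0.956 and 0.680. Nfia was highest at E18 (0.152, 1.04 and 0.308). The P2 cells had lower totals, and the median log2 of P2 over E14 for the 3000 genes with the highest mean was -0.61 (-0.19 after scaling each cell to 10000), with 87.9% of them lower. Genes lower at P2 are read against that shift. Mitochondrial genome genes went the other way, higher at P2 in 7 of 7 measured (median log2 1.34, 2.11 after scaling). The cause was not tested, and RNA quality was not assessed. Over all cells, early temporal genes were lower in 6 of 6 measured (median -2.39), below every random list, and late-born fate genes were higher in 5 of 6 (median 0.79). The late-born fate list holds photoreceptor genes, and precursors were 5 of 195 cells at E14 and 90 of 269 at P2. The G2/M list was lower in 17 of 17 (13 of 17 after scaling), with 9.60% of random lists lower still, and G1/S was lower in 18 of 18, below every random list. These values too are over all cells with that change in precursors, so they cannot be set against the 10x values of RPCs alone. The largest rise was Fabp7, a fatty acid-binding protein gene, with a log2 of 4.72: P2 photoreceptor precursors had a mean of 85.7 and late RPCs 0.352. Pkm, a pyruvate kinase gene, had a log2 of -2.69 over all Smart-seq2 cells, while in the 10x RPCs alone it was 0.54.

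For genes called in the 10x RPCs, 590.0 of 1107 had the same direction in Smart-seq2 between P2 and E14 (53.3%, exact 95% interval 50.3 to 56.3; 62.6% relative to the median shift). Between E18 and E14, where totals were alike, it was 437 of 547 (79.9%, 76.3 to 83.2). The Smart-seq2 side is over all cells, of which precursors were 2.56% at E14, 7.07% at E18 and 33.5% at P2. Both shares thus set a mix of classes against the RPCs of the 10x data. Genes are not independent replicates.

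The P14 mutant series asks what loss of Nfia, Nfib and Nfix in the progeny of progenitors that make Cre does. The labels do not give the deleted exons. A 3' tag outside the deleted part checks nothing, so these counts do not measure the deletion. Over all cells, Nfia was at 98.6 and 131 CPM in het replicates 1 and 2 and at 91.5 and 109.9 CPM in tCKO replicates 1 and 3. Nfib was at 124 and 135 CPM in het and 345 and 365 CPM in tCKO. Nfix was at 81.2 and 65.5 CPM in het and 77.2 and 106 CPM in tCKO. Within RPCs Nfib was lower in tCKO, at 468 and 504 CPM in het and 269 in both tCKO libraries, but did not pass the test (adjusted p = 0.0685). In bipolar cells it was higher, at 207 and 252 CPM in het and 1375 and 926 CPM in tCKO, with no test.

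**Figure D3:**
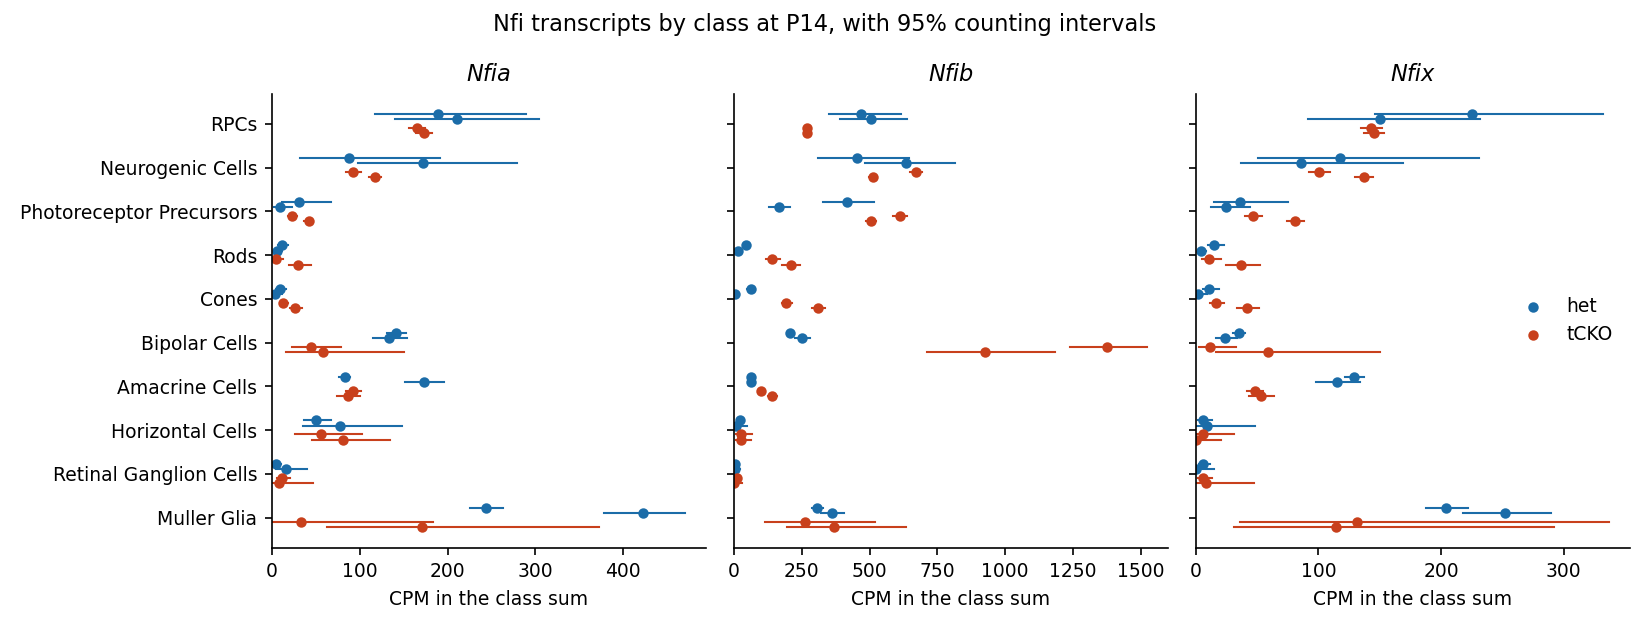
CPM of Nfia, Nfib and Nfix (x axes) in 10 annotated classes (y axis) of P14 retinas, each point 1 library with its exact 95% counting interval. In RPCs Nfib was at 468 and 504 CPM in het and at 269 CPM in both tCKO libraries, and in bipolar cells at 207 and 252 CPM in het and 1375 and 926 CPM in tCKO.

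The makeup of the retina differed between the genotypes. RPCs made up 0.808% ± 0.499 of het cells and 28.7% ± 1.31 of tCKO cells (SD, n = 2 each), and neurogenic cells 0.665% ± 0.411 and 21.4% ± 2.94. Photoreceptor precursors were 5.34% ± 6.33 and 14.4% ± 1.74. Bipolar cells, the interneurons between photoreceptors and ganglion cells, were 21.3% ± 7.01 in het and 0.815% ± 0.778 in tCKO. Müller glia were 6.88% ± 2.65 in het and 0.115% ± 0.0119 in tCKO. Rods were 23.0% ± 20.2 in het and 3.05% ± 0.703 in tCKO. The lowest UMI count of a deposited cell was 1776 and 546 in het replicates 1 and 2, and 1364 and 2588 in tCKO replicates 1 and 3. The rods of het replicate 2 had a median of 687 UMIs, below the lowest count of each other library. These shares are therefore not on equal terms. Among cells with at least 2588 UMIs, the highest minimum of the 4 libraries, rods were 2.30% in het and 2.33% in tCKO, but that floor lies above the median of rods in 3 of the 4 libraries and so removes most of their rods whatever the share. Amacrine cells (20.2% ± 12.4 and 11.5% ± 5.96) and cones (7.27% ± 2.09 and 6.27% ± 1.83) overlapped. With that floor they did not: amacrine cells were 30.6% ± 0.192 in het and 10.9% ± 5.17 in tCKO, and cones turned direction, at 3.05% ± 2.40 and 6.61% ± 2.31. The direction of RPCs (1.64% and 29.2%), precursors (0.4% and 13.4%), bipolar cells (14.9% and 0.375%) and Müller glia (17.7% and 0.131%) stayed with the floor. The floor kept 12.49% of the cells of het replicate 2, 46.09% of tCKO replicate 1, 71.23% of het replicate 1 and all of tCKO replicate 3. In het replicate 2 it lay above the medians of precursors (745.5 UMIs), cones (1338), bipolar cells (1507) and amacrine cells (1924) too. It removes most of those cells there, so values with the floor do not test the shares of these classes. In 7 of 12 classes the libraries of the genotypes did not overlap, 3 higher and 4 lower in tCKO; chance gives 33.3%, or 4 classes. With 2 against 2 libraries the exact permutation test cannot go below p = 0.333, so it called 0 classes. edgeR on cell numbers called 5: RPCs (log2 5.15, adjusted p = 0.0011), neurogenic cells (5.01, 0.0011), Müller glia (-5.89, 0.00105), bipolar cells (-4.69, 0.00135) and rods (-2.91, 0.0272). Shares are parts of a whole, so the larger shares of RPCs, neurogenic cells and precursors in tCKO lower those of other classes. Rods were 8.77% and 37.3% in het replicates 1 and 2, and 3.55% and 2.56% in tCKO replicates 1 and 3. A loss of rods among the remaining classes was not tested and is not shown by these calls.

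**Figure D4:**
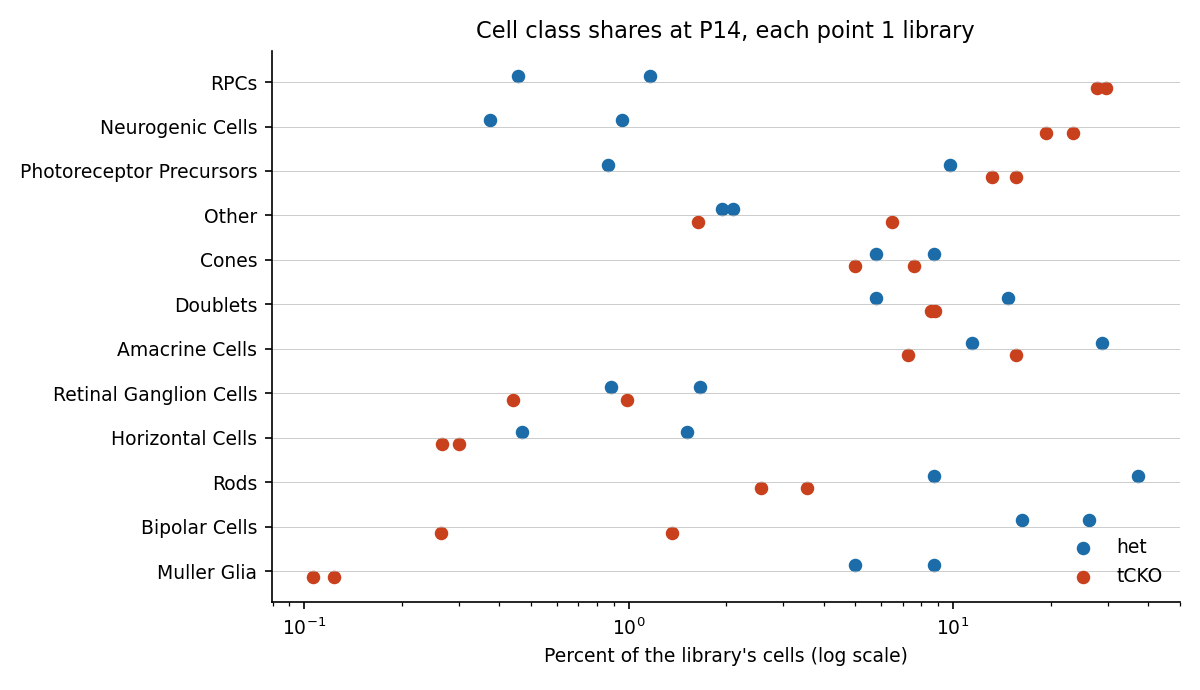
Percent of each library's cells in 12 annotated classes (x axis, log scale) for P14 het and tCKO retinas, each point 1 library. RPCs averaged 0.808% in het and 28.7% in tCKO, and Müller glia 6.88% and 0.115%.

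Whole-retina sums mix the shares of classes with changes inside them. Nfib rose by log2 1.51 ± 0.16 (adjusted p = 0.0109), from 127 ± 13.1 to 363 ± 23.5 CPM (n = 2 each). Nfia (-0.13 ± 0.23, adjusted p = 0.728) and Nfix (0.39 ± 0.22, adjusted p = 0.272) were not called. With the het level of Nfib in each class, the class makeup of the tCKO libraries alone gives a log2 of 1.225 where 1.451 was seen. The mitotic kinesin regulator Prc1 rose by 5.20 and cyclin B1 (Ccnb1) by 5.00. Igf2bp1 rose by 6.96, Fgf15 by 4.36, and the amacrine and horizontal fate genes Ptf1a and Foxn4 by 7.94 and 6.42. Grm6, the glutamate receptor gene of ON bipolar cells, fell by 6.15 ± 0.54 (adjusted p = 0.00846), from 135 ± 33.0 to 1.92 ± 1.24 CPM. Rlbp1 fell by 2.90 ± 0.18 (adjusted p = 0.00634), and the Müller glia water channel gene Aqp4 fell by 4.97. Krt73, a keratin gene, was higher by a ratio of 853 (95% counting interval 292 to 4137).

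In the whole retina the G2/M list rose in 20 of 20 genes and fell in 0 (20 and 0 adjusted over the list alone), and G1/S in 19 of 20, with 0 lower (20 and 0 adjusted over the list alone). The early temporal list rose in 8 of 16 and fell in 0 (11 and 0 adjusted over the list alone), and the neurogenic bHLH list rose in 10 and fell in 1 of 17 (10 and 2 adjusted over the list alone). The bipolar list fell in 16 and rose in 1 of 18 (16 and 1 adjusted over the list alone), and Müller glia fell in 8 and rose in 2 of 22 (10 and 2 adjusted over the list alone). In all 1769 of 15580.0 genes differed, 995 higher and 774 lower in tCKO, and 5225 had an unadjusted p under 0.05. The count was 389 without het replicate 1, 456 without het replicate 2 and 912 without tCKO replicate 3. Camera called 18 of 30 lists, 7 up and 11 down, and none held: the lowest adjusted p was 0.360 with an estimated correlation.

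Rods were tested to see whether the cells that form are typical. They gained cone transcripts and lost rod ones. Gngt2, the cone transducin gamma gene, rose by log2 3.85 ± 0.24 (adjusted p = 9.5e-07), from 143 ± 21.2 to 2064 ± 284 CPM (n = 2 each). Ccdc136, a gene of the cone list, rose by 4.17 ± 0.25 (adjusted p = 9.5e-07; 15.1 ± 0.716 to 272 ± 32.9 CPM), and Rxrg, a nuclear receptor gene of cones, by 5.31. Guca1a, which activates guanylate cyclase in photoreceptors, fell by 2.45 ± 0.22 (adjusted p = 2.7e-05), Guca1b fell by 1.90 and Gnat1, rod transducin alpha, fell by 1.43. Sox11, a gene of immature neurons, rose by 3.01. RPCs were 0.808% of het and 28.7% of tCKO cells. Free RNA from progenitors was not measured in rods, which limits Sox11 and the RPC core list below. Krt73 was at least 79.4-fold higher. Nfia, Nfib and Nfix were not called (adjusted p = 0.707, 0.0614 and 0.532).

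The cone list rose in 6 of 12 genes in rods and fell in 0 (7 and 1 adjusted over the list alone). The rod list fell in 9 of 22 and rose in 0 (19 and 0 adjusted over the list alone), and RPC core rose in 4 of 11 and fell in 0 (9 and 0 adjusted over the list alone). In all 256 of 8371 genes differed, 148 higher and 108 lower, with 1198 at an unadjusted p under 0.05 (145 to 1993 rods per library). The count was 86 without het replicate 2 and 101 without tCKO replicate 3. Camera called 16 lists, 11 up and 5 down, and none held: the lowest adjusted p was 0.332 with an estimated correlation.

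The transcripts of amacrine cells, a class of interneurons, also differed. Nfix fell by log2 1.30 ± 0.18 (adjusted p = 0.0041), from 123 ± 5.10 to 50.4 ± 4.87 CPM (n = 2 each), a call that ended without het replicate 1. Nfib rose by 0.94 ± 0.21 (adjusted p = 0.0422), a call that ended without het replicate 1, het replicate 2 or tCKO replicate 3, and Nfia was not called (-0.50 ± 0.38, adjusted p = 0.619). Fabp7, Hes5 and Sox11, genes of immature or progenitor cells, rose by 3.96, 3.35 and 2.95, and Ptf1a had a ratio of 286 (95% counting interval 78.7 to 2370). Vip, the neuropeptide gene of an amacrine subtype, fell by 4.66 ± 0.30 (adjusted p = 2.6e-05), from 78.1 to 2.80 CPM, and the gap junction gene Gjd2 fell by 2.43. Free RNA from other classes was not measured here, and progenitors held far more of the tCKO cells. Grm6, a bipolar cell gene, was lower in tCKO amacrine cells by a ratio of 24.9 (95% counting interval 8.31 to 123), and bipolar cells held a smaller share. The cholesterol synthesis list fell in 10 of 15 and rose in 0 (15 and 0 adjusted over the list alone), with the sterol sensor partner gene Insig1 at -2.01 ± 0.20 (adjusted p = 5.6e-04). The Notch pathway list rose in 6 of 14 and fell in 0 (8 and 0 adjusted over the list alone). In all 297 of 11649 genes differed, 170.0 higher and 127 lower, with 1862 at an unadjusted p under 0.05. The count was 37 without het replicate 1, 103 without het replicate 2 and 537 without tCKO replicate 1. Camera called 18 lists, 11 up and 7 down, and none held: the lowest adjusted p was 0.336 with an estimated correlation.

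The transcripts of cones differed too. Opn1mw, the medium-wavelength opsin gene, fell by log2 3.72 ± 0.32 (adjusted p = 0.001), from 3113 ± 902 to 236 ± 62.0 CPM (n = 2 each). Thrb, the thyroid hormone receptor gene of cones, fell by 1.99. Hes5, a Notch target gene, rose by 5.64 ± 0.49 (adjusted p = 0.00101), Ccnd1 by 3.49, Prdm1 by 3.10 and Otx2 by 1.66, again with free RNA from progenitors not measured. Krt73 was at least 70.5-fold higher. The cone list fell in 3 of 14 and rose in 0 (7 and 1 adjusted over the list alone), and the late temporal and gliogenic list rose in 5 of 20 and fell in 0 (13 and 1 adjusted over the list alone). Nfia, Nfib and Nfix were not called (adjusted p = 0.272, 0.348 and 0.244). In all 187 of 9753 genes differed, 88 higher and 99 lower, with 1504 at an unadjusted p under 0.05. The count was 65 without tCKO replicate 3 and 424 without het replicate 1. Camera called 15 lists, 9 up and 6 down, and none held: the lowest adjusted p was 0.328 with an estimated correlation.

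Tests of 3 further classes, added after the class sizes were seen, ask how the abundant tCKO progenitors compare with the few het ones. In RPCs (28, 62, 2607 and 1681 cells in het 1, het 2, tCKO 1 and tCKO 3) Rlbp1 fell by log2 2.75 ± 0.23 (adjusted p = 7.4e-06), from 658 ± 232 to 98.5 ± 8.96 CPM (n = 2 each). Crym fell by 2.50 ± 0.26 (adjusted p = 6.2e-05) and Otx2 fell by 1.78. Ndufa4l2, a mitochondrial gene induced by low oxygen, rose by 3.90 ± 0.31 (adjusted p = 5.7e-06), from 43.9 ± 1.89 to 657 ± 12.0 CPM. Nfia and Nfix were not called (adjusted p = 0.826 and 0.657). The median log2 of all genes was 0.16, and 0.09 with the size factors of DESeq2. The Müller glia list fell in 10 of 20 and rose in 0 (11 and 0 adjusted over the list alone), the rod list fell in 11 of 22 and rose in 0 (16 and 0 adjusted over the list alone), and G1/S rose in 7 of 20 and fell in 0 (14 and 0 adjusted over the list alone). In all 198 of 10959 genes differed, 80.0 higher and 118 lower, with 1421 at an unadjusted p under 0.05. Rods and Müller glia held smaller shares of the tCKO cells, and free RNA from them in RPCs was not measured. The count was 58 without het replicate 2, 70.0 without tCKO replicate 1, 77 without tCKO replicate 3 and 90.0 without het replicate 1. Camera called 10 of 28 lists, 3 up and 7 down, and none held: the lowest adjusted p was 0.401 with an estimated correlation.

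In neurogenic cells (23, 51, 1813 and 1332 cells) 36 of 10773 genes differed, 21 higher and 15 lower, with 862 at an unadjusted p under 0.05. The split turned with DESeq2's own test, at 6 higher and 47 lower. Ndufa4l2 was at least 18.5-fold higher in tCKO. The count was 5 without het replicate 1, 11 without het replicate 2 and 21 without tCKO replicate 3. Camera called 4 of 29 lists and none held: the lowest adjusted p was 0.967 with an estimated correlation. In photoreceptor precursors (53, 524, 1233 and 885 cells) 58 of 10213 genes differed, 34 higher and 24 lower, with 1131 at an unadjusted p under 0.05. Ccdc136 rose by 4.07 ± 0.35 (adjusted p = 4.2e-04), from 38.7 ± 17.0 to 598 ± 13.7 CPM (n = 2 each), and Opn1sw, the short-wavelength opsin gene, by 3.70. The cone list rose in 6 of 14 and fell in 0 (9 and 0 adjusted over the list alone), and the rod list fell in 1 of 22 and rose in 0 (9 and 0 adjusted over the list alone). The count was 18 without het replicate 2, 90.0 without tCKO replicate 1 and 258 without het replicate 1. Camera called 10 lists, 9 up and 1 down, and none held: the lowest adjusted p was 0.530 with an estimated correlation.

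Bipolar cells (1614, 873, 128 and 15 cells) and Müller glia (538, 267, 10 and 7 cells) were too few in tCKO for a test under the set minimum, and have values only. In bipolar cells Grm6 was at 707 and 543 CPM in het and at 172 (exact 95% interval 126 to 229) and 132 (60.5 to 251) CPM in tCKO. In Müller glia Rlbp1 was at 3254 and 3232 CPM in het and at 1712 (1279 to 2245) and 1255 (912 to 1684) CPM in tCKO. Glul, the glutamine synthetase gene, was at 6190 and 3730 CPM in het and at 461 and 769.9 CPM in tCKO. Counting intervals cover counting error only.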

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

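The tests of the batch split and both tests of the cone transcripts in rods were chosen after the results were seen, as was the test of rods against amacrine cells. The changes of different cell classes under the same contrast were compared with an interaction term. It has 2 libraries per class and group and borrows spread across genes. Its errors are computed from the same F statistic as its p values. Both rest on that borrowed spread, and the errors are no separate measure of it.

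The change from E14 to P2 differed between neurogenic cells and RPCs for 2428 of 12360 genes, 1107 higher and 1321 lower in neurogenic cells, with 3695 at an unadjusted p under 0.05. The count was 1497 without E14 replicate 2 and 1531 without P2 replicate 3. Spc25, a kinetochore gene, had a difference of -1.71 ± 0.07: it went from 301 to 666 CPM in RPCs and from 448 to 306 CPM in neurogenic cells. Ube2c differed by -1.49 ± 0.06 (RPCs 413 to 758, neurogenic cells 666 to 433 CPM). Hes6 differed by -1.15 ± 0.05, with a larger gain in RPCs, and Tuba1b by -1.05 ± 0.05. Nfib gained more in neurogenic cells (0.98 ± 0.15), while Nfia and Nfix did not pass (adjusted p = 0.532 and 0.055).

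The effect of tCKO differed between amacrine cells and rods for 237 of 11007 genes, 67 higher and 170.0 lower in amacrine cells, with 1338 at an unadjusted p under 0.05. The count was 396 without het replicate 1, 99 without tCKO replicate 1 and 43 without tCKO replicate 3. Ccdc136 rose in rods, from 15.8 to 282 CPM, and was at 72.2 and 67.1 CPM in amacrine cells (difference -4.25 ± 0.29). Gng13 (-5.02 ± 0.39), Camk2b (-3.68 ± 0.29), Rxrg (-5.36 ± 0.56) and Ece1 (-4.89 ± 0.52) also gained more in rods. Nfix differed by -2.43 ± 0.54 (adjusted p = 0.0189), and Nfib and Nfia did not pass (adjusted p = 0.0544 and 0.766).

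The first pattern weighed is the rise of rod transcripts in P2 RPCs. Free RNA from rods and precursors predicts rod transcripts in other cells too, and over the 17 genes the median log2 ratio of UMIs per cell, P2 RPCs over P2 amacrine cells, was 0.8642 (0.7918 to 0.9365 in the libraries), so RPCs held more than amacrine cells, by less than the 2 times set as the bound for each library. That is close to the bound: from the mean UMIs per cell of both libraries, 6 of the 17 genes were above 2 times and the median log2 was 0.895. Within P2 replicates 2 and 3 alone, 7 and 8 genes were above 2 times, and 1 and 2 genes had no UMI in amacrine cells. Precursors annotated as RPCs predict a similar needed share from each gene, and the upper over the lower quartile of that share was 1.804, with 3.833% for Nt5e and 695.6% for Gnat1, whose gain was 1.31 CPM. The median needed share was 17.9% (Nr2e3), with quartiles of 13.5% (Prph2) and 24.4% (Pde6g). Fabp7, which is outside the rod list, was at 6858 and 6138 CPM in P2 precursors. In late RPCs it was at 83.9 and 77.2 CPM, near the 84.8 and 76.6 CPM of amacrine cells. That is low for such a share of precursors with this Fabp7 level, but it is 1 gene and does not settle the source. Free RNA and precursors annotated as RPCs both remain candidate sources, and they do not exclude each other. Rod genes switching on in RPCs with age also stays open, untested.

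The second pattern is the 25 of 32 genes, such as Rps6 and Eno1, that fell at least 4-fold from E18 to P2 in RPCs and lay nearer to E18 at P5 (78.12%, exact 95% interval 60.03 to 90.72, against 53.89% of 4051 uncalled genes). All 25 were lower at P2 in neurogenic cells, precursors, amacrine cells and cones too. These classes come from the same libraries, so a batch difference and a true dip shared by the classes would both give this. The P0 library lay nearer to P2 for 24 of the 32 (and for 2290 of the 4051 uncalled genes). A difference between library batches may contribute, though the labels give no batch. Reads shared with similar genes are a possible route. Of the 25, 60.0% shared at least 10% of the 31-mers in their last 500 bases with other genes, 50.14 points more than uncalled genes (9.857%). The uncalled genes were not matched to the 25 in level or kind. The excess therefore does not show that shared reads lowered the counts. In Smart-seq2 their median log2 from E18 to P2 was -0.37, against -0.51 for uncalled genes, but the means of Eno1 (56.4 to 6.04) and Hspa8 (33.0 to 3.64) were far lower at P2 by that method too. A true dip around birth stays open, untested.

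The third pattern is the gain of cone transcripts in tCKO rods. Against free RNA from cones, the gain in UMIs per cell in amacrine cells was a median of 0.04006 times that in rods over 6 genes (-0.121 to 0.06924), with Gngt2 at 7.97 in rods and 0.552 in amacrine cells. Against cones annotated as rods, the needed share of cones was 72.9% for Rxrg, 29.5% for Gngt2, 1.00% for Arr3 and -0.0197% for Pde6h, a quartile ratio of 14.73 over 12 genes. An effect of the genotype on rods, or rods caught at a younger stage, may explain it and was not tested. Precursors annotated as rods were not tested either: they were 14.4% of tCKO cells, and 6 of 14 cone genes rose in them.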

How the results depend on the processing

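The block with swapped numbers and all tests of tCKO RPCs, neurogenic cells and precursors, and of rods against amacrine cells, were chosen after the data were seen. Over all alternatives, 11299 of 12839 values of named genes kept their direction and their side of the threshold, 1103 fell short of it, 437 passed it and 0 reversed. For gene lists 2675 of 3073 kept both, 260.0 fell short, 121 passed and 17 reversed. For Smart-seq2 genes 34 of 78 stayed alike and 44 moved. For classes 271 of 287 kept both, and for counts of genes or classes 101 of 161 stayed within 1.5 times. Using DESeq2's size factors in edgeR left each count of genes within 1.5 times.

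DESeq2's own test called 2233 genes between P2 and E14 RPCs, 880 between E18 and E14, 742 between P2 and E18, 953 in neurogenic cells by age, 3165 in the whole retina and 152 in rods. Of the first, 2203 were also called by edgeR. Its split leaned lower in tCKO RPCs (57.0 higher and 227 lower, against 80.0 and 118 by edgeR) and in tCKO neurogenic cells (6.00 and 47.0, against 21 and 15). The split turned for the age trend, with 2283 higher and 1980 lower against 1895 and 2330 by edgeR. It also turned in the whole retina, with 1500 and 1665 against 995 and 774. With no filter on low counts more genes were called in rods (669), amacrine cells (851), cones (733), tCKO RPCs (431), tCKO neurogenic cells (137) and precursors (305). With cells of at least 1000 UMIs the whole retina gave 2927 and rods 122. With only the libraries of the compared ages E18 against E14 gave 1739 and P2 against E18 5676. Ages split into before and after birth gave 1605 genes for the trend. The causes were not tested.

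A replicate block was fitted for P2 against E18 on their 4 libraries alone, whose labels share the numbers 2 and 3. It called 5424 genes, and 6033 with number 2 of one age paired with 3 of the other, against 5676 on these libraries with no block. The correlation of the paired differences was -0.291 over 4976 genes, so the numbers give no sign of a shared origin.

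Leaving out each library in turn gave 2588 to 7189 genes for P2 against E14, 792 to 5732 for E18 against E14, 262 to 517 for P2 against E18, 3221 to 4804 for the trend and 1589 to 3949 for neurogenic cells by age. For tCKO against het it gave 389 to 2259 in the whole retina, 86 to 364 in rods, 37 to 537 in amacrine cells, 65 to 424 in cones, 58 to 90 in RPCs, 5 to 40 in neurogenic cells and 18 to 258 in precursors. It gave 1497 to 2032 for neurogenic cells against RPCs, 43 to 396 for rods against amacrine cells, and 8 to 11 classes apart, where leaving out a library can only add classes and chance alone sets 2 in 3 apart. Where this leaves a group with 1 library, the spread is pooled and the lone library is assumed to vary like the others. These fits have fewer libraries, and the cause of the higher counts was not tested.

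Some lists reversed between settings, given here as adjusted p values of camera. For the trend, G2/M had 4.822e-09 with at least 1000 UMIs and 6.005e-09 to 0.9789 over the left-out libraries, the lowest without P14, and vascular had 0.7841 and 4.511e-12 to 0.7353, the highest without P14. Vascular in neurogenic cells had 0.9466 with no filter. In rods, bipolar had 0.5521 with no filter and red blood cell 0.008122 with at least 1000 UMIs. Over left-out libraries, the whole retina had 0.001708 to 0.8121 for immediate early and 0.0003416 to 0.9473 for interferon, reversed without het replicate 2 (0.0147) and tCKO replicate 3 (0.01431). Amacrine cells had 5.63e-06 to 0.8182 for bipolar, 4.376e-09 to 0.8097 for immediate early and 2.412e-10 to 0.9721 for horizontal, reversed without het replicate 1 (0.8182), het replicate 2 (0.04179) and tCKO replicate 3 (0.9721). Cones had 0.0009512 to 0.06577 for immediate early, 0.0002176 to 0.7165 for bipolar and 0.002765 to 0.7222 for amacrine, reversed without het replicate 1 (0.0009512) and het replicate 2 (0.001629 and 0.002765). The tCKO neurogenic cells had 3.297e-06 to 0.5857 for rod and 0.005783 to 0.9138 for neurogenic bHLH, reversed without tCKO replicate 1 (0.08188) and tCKO replicate 3 (0.0132). The causes were not tested.

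With cells at or above the highest minimum UMI count (2588), the difference in the share of rods was 0.02843 points instead of -19.99. Rods had medians of 2335 and 687 UMIs in het and 1924 and 4399 in tCKO, so this floor removes most rods of 3 libraries and does not test their share. Without it the lowest UMI counts of the libraries differ, at 1776 and 546 in het and 1364 and 2588 in tCKO. The difference of -19.99 points is thus not on equal terms either. The floor also moved RPCs (tCKO over het 17.9 instead of 35.5), bipolar cells (het over tCKO 39.7 instead of 26.1), horizontal cells (5.95 instead of 3.50), cones (3.56 points, the other direction), amacrine cells (-19.7 instead of -8.68), precursors (tCKO over het 33.6 instead of 2.69) and Müller glia (het over tCKO 135 instead of 59.8), and 10 classes were apart instead of 7. In het replicate 2 it lay above the medians of precursors (745.5 UMIs), cones (1338), bipolar cells (1507) and amacrine cells (1924), so these moves do not test their shares. edgeR on cell numbers called 5 classes where the exact test called 0. For Smart-seq2, the share of 10x calls with the same direction was 37.85% with the median over cells, 57.63% with each cell scaled to 10000, and 62.6% relative to the median of the 3000 genes. The alternatives for bipolar cells, Müller glia and rods against bipolar cells were not run, since these classes were under the set minimum of cells.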

Other observations

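Where the tCKO RPCs stand on the wild-type time course was compared over the 2024 genes that differed between P2 and E14 RPCs with an average logCPM of at least 5. The value is a rank correlation between libraries of log2 CPM minus the mean of the wild-type RPC sums. The 2 tCKO libraries had their highest value with E18 replicate 2 (0.636 and 0.604), against 0.595 and 0.543 with E18 replicate 3, 0.587 and 0.528 with P2 replicate 3 and 0.546 and 0.532 with P5. The 2 E18 replicates lay farther apart than E18 replicate 3 and P2 replicate 3, so these values do not set E18 apart from P2. The het libraries, with 28 and 62 RPCs, had theirs with P2 replicate 3 (0.443 and 0.349), and nearly the same with P5 (0.432 and 0.349). Genes are not independent, and no test was made. The 2 data tables differ in genes such as mt-Co2, so levels are not compared between them gene by gene.

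Fabp7 was higher in P2 photoreceptor precursors than in late RPCs by both methods. In the Smart-seq2 cells it had a mean of 85.7 in precursors and 0.352 in late RPCs. In the 10x data it was at 6858 and 6138 CPM in the precursors and 83.9 and 77.2 CPM in the late RPCs of the P2 libraries, with rods at 4058 and 3382 CPM and cones at 1577 and 1608 CPM.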
